A study of Caenorhabditis elegans with 8 samples.

How the data were processed

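iCLIP is a crosslinking method in which RNA bound to a protein in living material is fixed to it by ultraviolet light, purified with the protein and sequenced. Here it was applied to larvae of the nematode Caenorhabditis elegans that carried an epitope-tagged copy of FOG-3, a protein of the germline sperm fate pathway, and 4 libraries purified with the epitope antibody were set against 4 libraries from the same worms taken through the protocol with that antibody left out. Per the labels' protocols the material was lysed by ball milling. The design text calls both sets of 4 biological replicates.

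The authors deposited 1 table of raw read counts per gene ID, with a column for each library. Per the submitters' processing notes, STAR 2.4.2 and HTSeq were used. The genome build, the annotation, the strand setting, the treatment of reads that map to several places and the use of random barcodes to collapse PCR copies are not given in the sources used here. If copies were not collapsed, the reads are not independent molecules, and every interval and floor below covers counting error only. The column names give the group of each library and a 4-letter tag that appears in no label, so a column could be given its group but not its numbered sample. The libraries are therefore called by their tags, and the p-values measure the spread between these libraries.

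The table names genes only by WormBase ID. None (0) of these IDs was found in the gene table used as reference, which lists 46926 genes by other identifiers, and the file itself pairs no ID with a symbol. Gene symbols, chromosomes and gene classes were therefore not used here. The 14 gene lists that had been fixed before the data were examined (oocyte, sperm, sex determination, meiosis and somatic cell types among them), the test for the X chromosome and the settings limited to protein-coding genes were not analysed for this reason. For the same reason only the part of the fixed rule for named genes that needs no symbol was applied: the 10 IDs of smallest p in each direction among called IDs whose CPM did not overlap between groups, cut to 2 per direction because IDs without symbols say little. The parts of the rule that name list members and fixed genes could not be applied. The genes with the most reads, also part of that rule, are described without their IDs.

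Of the rows, 2 name no gene and hold reads outside annotated genes and reads that overlapped several genes. They stayed out of library sizes and tests. Their mean shares of all reads were 11.5% and 0.648% in FOG-3 libraries and 3.70% and 0.380% in controls. The other 12240 rows held 14964 to 186739 reads per library, so that a single read was worth between 5.36 and 66.8 CPM (counts scaled to library size). A count of 0 allows a level of up to 3 reads, which is 16.1 CPM in the deepest and 200.5 CPM in the shallowest library. These values leave out the TMM factors that were applied to the CPM of single gene IDs below. On that scale the floors are higher in controls and lower in FOG-3 libraries. Exact Clopper-Pearson intervals at the 95% level are given for shares of single libraries.

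Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, group as the only term, TMM factors, library sizes over all gene rows). Rows were kept by edgeR's default filter (minimum count 10, minimum total 15), which left 886 rows. A row was called at a Benjamini-Hochberg adjusted p under 0.05. CPM of single gene IDs are TMM-scaled. Standard errors of log2 fold changes are approximate: the size of the fold change divided by the square root of its F statistic. Pooled folds divide the reads of a group by the sum of its TMM-scaled library sizes, and a gene with 0 reads in all 4 controls was set to 3 reads over the control group, which makes its fold a lower bound. Library measures were compared with a two-sided exact permutation test of the difference of means over 70 splits. The smallest p this design allows is 0.0286, and 8 measures formed one family for the Benjamini-Hochberg adjustment. The number of genes at equal depth is the expected number with at least 1 read in 14964 reads drawn without replacement.

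The fit was tested on simulated counts drawn from the real library totals and mean shares, with 200 rows changed. The filter left 945 rows of this table. All raised rows passed it, but only 38 of the 50 rows lowered 2-fold and 21 of the 50 lowered 4-fold did. The fit recovered 66% of the 2-fold increases, 68.4% of the 2-fold decreases that passed the filter and all (100%) of the 4-fold changes that did. It called 5 of 786 unchanged rows, and 0 of 1026 rows in a table with no changes. As many rows were raised as lowered, 50 in each direction at 2-fold and at 4-fold. In the real libraries the most abundant row held 49.8% of gene-assigned reads in controls and 27.9% in FOG-3. How TMM scaling behaves under such a shift was not tested by the simulation. Its rates therefore cannot be carried over to the real calls, the lower ones in particular.

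Alternatives were DESeq2 1.42.0, limma 3.58.1 (voom, with and without library weights), other scalings, other filters, stricter thresholds and leaving out each library in turn. Scaling on the most abundant row, TMMwsp factors, the size factors of DESeq2 in edgeR, thinning to equal depth, leaving out rows with identical counts leaving out the 2 shallowest controls, and all alternatives for read shares and genes at equal depth were chosen after seeing the data.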

Results

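The series measured RNA associated with FOG-3, a protein required for germ cells to take the sperm fate, in fourth-stage (L4) larvae. It held 4 FOG-3 libraries, purified through the epitope tag, and 4 control libraries made without the antibody, which show the RNA that is carried through the protocol without specific purification. All results come from read counts per gene ID.

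FOG-3 libraries were deeper than controls. The FOG-3 libraries held 76790, 80529, 97054 and 186739 gene-assigned reads, and the controls held 14964, 18676, 30631 and 74892. The mean of log10 reads was 5.01 ± 0.18 (SD, n = 4) in FOG-3 and 4.45 ± 0.31 (SD, n = 4) in controls, a difference that gave p = 0.0286 in an exact two-sided permutation test, the smallest value possible here. Without any 1 of the 4 FOG-3 libraries (CGGA, GGCA, GGTT or TGGC) the exact permutation p was 0.057. Of 12240 gene IDs with a read in any library, 6854 had reads only in FOG-3 libraries, 359 only in controls and 5027 in both. These detection counts move with depth. At an equal depth of 14964 reads, 3406 ± 285 gene IDs (SD, n = 4) were expected in FOG-3 libraries and 1313 ± 325 in controls, a ratio of 2.59 (exact permutation p = 0.0286). The deepest control, with 74892 reads, gave 1692 gene IDs at that depth, and the shallowest FOG-3 library, with 76790 reads, gave 3306. Equal depth does not make these numbers independent of composition. The most abundant gene IDs took a larger share of the reads in controls, which left fewer reads for all others.

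The controls were dominated by a few genes and the FOG-3 libraries were not dominated to the same degree. A single gene ID took 49.8% ± 6.9 (SD, n = 4) of gene-assigned reads in controls and 27.9% ± 2.5 in FOG-3 libraries. The 9 next most abundant gene IDs took 27.6% ± 2.9 in controls and 13.98% ± 2.73 in FOG-3 libraries. Gene IDs too rare to be tested one by one took the opposite course, with 6.54% ± 2.38 of reads in controls and 25.9% ± 3.8 in FOG-3 libraries, a ratio of 3.96. The remaining tested gene IDs held 16.1% ± 2.1 in controls and 32.3% ± 1.9 in FOG-3. These shares make up the whole of the gene-assigned reads, so a smaller share of the most abundant gene IDs raises the others. Shares of the rarer classes without the most abundant gene IDs were not computed. In each of these classes every FOG-3 library lay on the same side of every control (exact permutation p = 0.0286, adjusted p = 0.0286 over 8 measures).

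**Figure D1:**
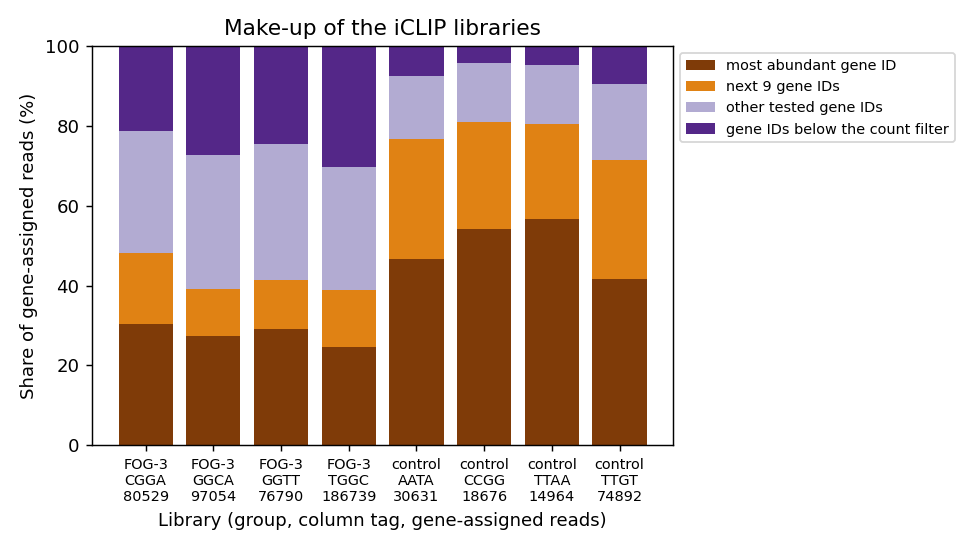
Stacked bars give the percent of gene-assigned reads of each of the 8 libraries that fell in the most abundant gene ID, the next 9, the other tested gene IDs and gene IDs below the count filter; group, tag and read total stand under each bar. The most abundant gene ID took 24.6% to 30.4% of reads in FOG-3 libraries and 41.6% to 56.7% in controls.

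Reads outside annotated genes and reads overlapping several genes also made up larger shares of all reads after purification of FOG-3. Reads outside genes made up 11.5% ± 1.2 (SD, n = 4) of all reads in FOG-3 libraries and 3.70% ± 1.41 in controls (exact permutation p = 0.0286). The lowest FOG-3 library had 9.73% (95% interval 9.54% to 9.92%) and the highest control 5.54% (5.38% to 5.70%). With the 10 most abundant gene IDs left out of the total, the ratio of the means fell from 3.11 to 1.29. The shares were then 18.4% ± 0.74 and 14.2% ± 2.5 (SD, n = 4, exact permutation p = 0.0286), with 17.3% in the lowest FOG-3 library and 17.1% in the highest control. Reads overlapping several genes made up 0.648% ± 0.053 of all reads in FOG-3 libraries and 0.380% ± 0.073 in controls (exact permutation p = 0.0286). This share was not recomputed without the 10 most abundant gene IDs, so no increase apart from them is shown.

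Libraries of a group resembled each other more than those of the other group. Across the 886 tested gene IDs, which are not independent replicates, Pearson correlations of log2(CPM + 50) ran from 0.88 to 0.94 between FOG-3 libraries, from 0.84 to 0.90 between controls and from 0.43 to 0.62 between groups. Chi-square per degree of freedom between libraries ran from 1.55 to 2.47 within FOG-3, from 1.66 to 5.35 within controls and from 5.48 to 22.6 between groups, where reads that are PCR copies would also raise it. Each library was counted as its own replicate, as the design text has it.

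The main comparison asks which RNAs were recovered with FOG-3 above the level in the controls. Of 886 gene IDs tested, 401 were higher and 244 lower in FOG-3, and 241 did not pass the threshold (edgeR quasi-likelihood test with TMM scaling, adjusted p under 0.05). The split moved to 596 higher and 84 lower with total counts alone, and to 706 higher and 6 lower when each library was scaled on its most abundant gene ID. The higher gene IDs had a median pooled fold of 5.88 (quartiles 3.83 and 11.6), and 123 of them exceeded 10-fold, all with TMM scaling. Their median fitted log2 fold change was 3.08 with TMM, 2.04 with limma-voom, 4.21 with total counts and 4.89 when scaled on the most abundant gene ID. Of these 401, 69 had no read in any control, so their folds entered as lower bounds, and 199 more had 1 to 3 control reads in all. Normalised counts did not overlap between the groups for 360 of the 401 higher and 185 of the 244 lower gene IDs. Over all tested gene IDs that share was 64.6%. Chance would give 2.86% for gene IDs that were not chosen by their level. The filter favoured gene IDs high in 1 group, however. One with no control read could pass it only through all 4 FOG-3 libraries, which fixes that the groups do not overlap. The 2.86% is therefore not the chance share here.

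All 10 of the most abundant gene IDs were among those called lower with TMM scaling, a call that most of the 244 lost under scaling on the most abundant gene ID. With TMM the 10 fell by 1.69 to 2.60 on the log2 scale. The most abundant fell by 2.15 ± 0.24 with TMM (SE, 4 libraries per group, edgeR adjusted p = 4.3e-17). Its share of gene-assigned reads was 49.8% in controls and 27.9% in FOG-3 libraries, a ratio of 0.56. The rest of its fall comes from the TMM factors, which were 0.593 to 0.716 in controls and 1.47 to 1.66 in FOG-3 libraries. The SE and p leave out the uncertainty of this scaling. The 244 lower gene IDs had a median log2 fold change of -1.61 with TMM (quartiles -1.99 and -1.25), -0.43 with DESeq2, -0.37 with total counts and 0.42 when scaled on the most abundant gene ID, where 196 of the 244 lay above 0. They had a median of 64 reads over the 4 controls, where the higher gene IDs had a median of 2. The higher gene IDs, chosen on these same libraries, held 14.9% ± 1.3 of gene-assigned reads in FOG-3 libraries and 0.863% ± 0.309 in controls. The lower ones held 52.0% ± 4.7 and 90.0% ± 3.4.

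Among the higher gene IDs, WBGene00044503 had the smallest p. It had 75 to 175 reads in every FOG-3 library and none (0) in any control, with 670.2 ± 114.6 CPM (SD, n = 4) in FOG-3. Its pooled level was at least 20.5-fold higher in FOG-3, with an edgeR adjusted p of 3.5e-19. WBGene00001526 followed, with 837.3 ± 133.0 CPM in FOG-3 from 560 reads and 87.7 ± 98.6 CPM in controls from 5 reads. Its log2 fold change was 3.92 ± 0.46 (SE, edgeR adjusted p = 2.4e-16).

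Among the lower gene IDs, WBGene00014692 had 199 ± 44 CPM (SD, n = 4) in FOG-3 and 1611 ± 331 CPM in controls. Its log2 fold change was -3.10 ± 0.24 (SE, edgeR adjusted p = 4.8e-35). WBGene00004567 had 1839 ± 487 CPM in FOG-3 and 11055 ± 1924 CPM in controls, a log2 fold change of -2.60 ± 0.21 (SE, edgeR adjusted p = 1.7e-33). These 4 gene IDs kept their direction and passed the threshold in all 21 alternative fits that tested them, but not their size. Over these fits the log2 fold change ran from -3.26 to -1.06 for WBGene00014692 and from -2.72 to -0.53 for WBGene00004567. It ran from 3.29 to 5.81 for WBGene00001526 and from 4.37 to 9.44 for WBGene00044503, whose fitted value depends on the prior count.

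**Figure D2:**
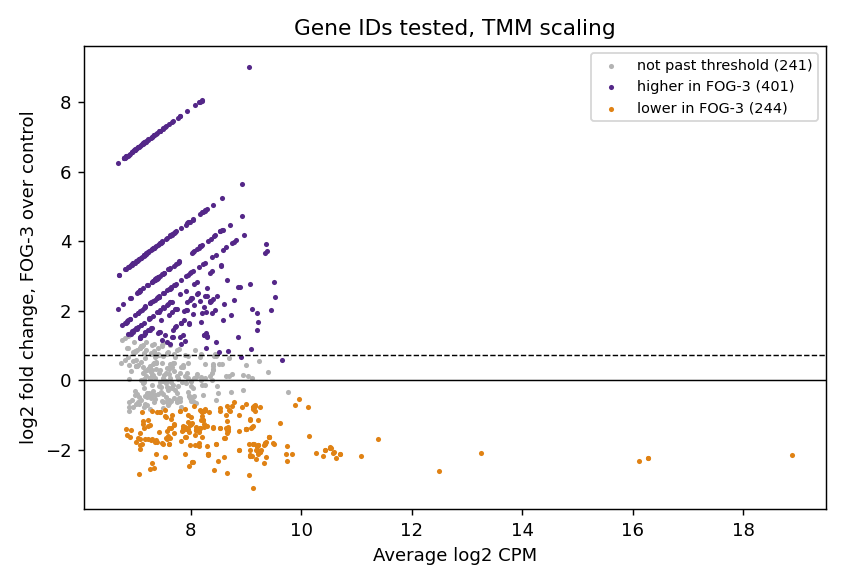
Each point is one of 886 tested gene IDs, with average log2 CPM on the horizontal axis and the fitted log2 fold change of FOG-3 over control on the vertical axis; the dashed line is the median of all tested gene IDs, 0.74. The 401 higher gene IDs lie in streaks set by their few control reads (fitted values with no control read depend on the prior count), and the 10 most abundant gene IDs are among the 244 lower ones with TMM, of which 6 stayed lower under every scaling.

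The split between higher and lower calls moved with the scaling, as did the median of all tested gene IDs. This median log2 fold change was 0.74 with TMM, 1.94 with total counts alone and 2.68 when each library was scaled on its most abundant gene ID. The size factors of DESeq2 gave 588 higher and 92 lower gene IDs in edgeR, and DESeq2's own test with them gave 562 and 87. Under scaling on the most abundant gene ID, 64 of the 244 gene IDs called lower with TMM passed as higher. Leaving out the deepest control, TTGT, gave 577 higher and 120 lower.

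All 401 gene IDs called higher with TMM were also called higher under each of the other 5 scalings, each of which gave a higher median over all tested gene IDs than TMM did, while 6 of the 244 were called lower under all of them. WBGene00014692 and WBGene00004567 are among those 6.

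**Figure D3:**
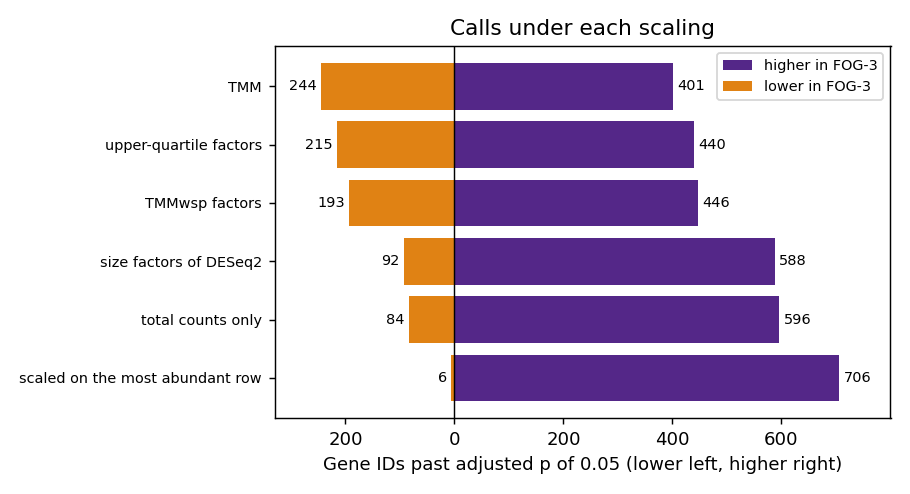
Bars give the number of gene IDs past an adjusted p of 0.05, higher in FOG-3 to the right and lower to the left of 0, for 6 scalings of the same 886 gene IDs (all tested with edgeR). Lower calls ran from 244 with TMM to 6 when libraries were scaled on the most abundant gene ID, and higher calls from 401 to 706.

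Some of the lower calls repeat one another. Among the 1460 gene IDs with at least 50 reads in total, 48 had exactly the same counts as another gene ID in all 8 libraries, in 20 sets. They include a pair among the 10 most abundant gene IDs, which each fell by 2.24 ± 0.22 (SE) on the log2 scale under TMM (edgeR adjusted p = 9.2e-22). The edgeR fit called this pair lower under every scaling. Taken per library, however, the ratio of its reads to those of the most abundant gene ID did not separate the groups. This ratio was 0.157 ± 0.031 in FOG-3 libraries and 0.175 ± 0.037 in controls (SD, n = 4, exact permutation p = 0.43). Such a partner was found for 33 of the 244 lower gene IDs (13.5%) and 2 of the 401 higher ones (0.499%), a difference with p = 7.3e-13 in a two-sided Fisher's exact test across gene IDs, which are not independent. The 244 lower gene IDs held 224 distinct count profiles, and the 401 higher ones 400. These are upper limits, since some gene IDs counted as distinct differ by only a few reads.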

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

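The tests of depth, dilution and reads outside genes in this part were chosen after the results were seen, and the last pair were reworded after earlier forms had given their results. As shares of all reads, 2 measures outside the gene counts stood above the controls in every FOG-3 library. They were reads outside annotated genes, with a mean of 11.5% against 3.70%, and reads overlapping several genes, with a mean of 0.648% against 0.380%. The share of reads overlapping several genes was not recomputed without the most abundant gene IDs, so no increase apart from them is shown. No library stood apart from the others of its group by Dixon's test in the 23 groups of 4 values tested.

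Part of the higher share of reads outside genes may come from the abundant gene IDs taking fewer reads in FOG-3 libraries. With the 10 most abundant gene IDs left out of the total, the ratio of the group means fell from 3.11 to 1.29. A difference remained, with every FOG-3 library above every control (exact permutation p = 0.0286), which an earlier form of the test read as against the abundant gene IDs being the whole cause. The lowest FOG-3 library lay only 1.01 times above the highest control, so whether the remainder comes from abundant gene IDs beyond these 10 or from FOG-3-associated RNA outside annotated genes cannot be told apart. Which regions these reads came from was not tested.

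The calls of both directions, 645 with TMM of which 244 were lower, were set against 35 splits of the 8 libraries. Only 1 split (the real one) gave as many, and the highest of the others gave 0. The real split always counts as 1, and every other split mixes both groups, which widens the spread and lowers the calls. The test therefore cannot exclude chance by itself, for the 244 in particular. For the 244, thinning to equal depth moved their median log2 fold change from -1.61 to -0.78. It moved that of all tested gene IDs alike, from 0.74 to 1.56. The 244 stayed below this median at equal depth. They were chosen on these same reads, which thinning only samples, so this says nothing for or against read number. The value of -0.78 lay between the marks set for and against depth, so depth stays open. Whether the median of the 244 lay below 0 moved with the scaling. Their median was -1.61 without the 2 shallowest controls (256 lower calls, 233 of them among the 244) and -0.91 without the deepest control, TTGT. The median of all tested gene IDs was then 0.86 and 1.79. A link of depth with the make-up of the controls stays open. One dilution by FOG-3-associated RNA may also account for most of the 244, though not clearly for all. When libraries were scaled on the 244 alone, 11.9% still differed between groups (18 higher and 11 lower, edgeR p adjusted over the 244). Under 1 factor for all 244, few would pass an adjusted p, so these gene IDs argue against it. The share lay between the 5% set for such a dilution and the 20% set against it, so a dilution of most of the 244 stays open. The earlier form, scaled on the most abundant gene ID, gave 28.8% (64 higher and 6 lower of 243), past that 20%, but it passes the error of 1 gene ID on to all others, so a loss of specific RNAs and this dilution cannot be told apart. Reads shared between similar genes were searched only as identical counts, found for 33 of the 244, and stay open for the others.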

How the results depend on the processing

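Alternatives chosen after seeing the data were TMMwsp, the size factors of DESeq2 in edgeR, scaling on the most abundant gene ID, thinning, and leaving out identical gene IDs or the 2 shallowest controls, and all for read shares and genes at equal depth. The 401 higher and 244 lower calls stayed within 1.5 times of the main counts with upper-quartile and TMMwsp factors, voom with and without weights, a threshold of 0.01, a 2-fold minimum, without identical gene IDs and without the 2 shallowest controls. Lower calls were 87 with DESeq2, 92 with its size factors in edgeR, 84 with total counts and 92 after thinning to equal depth. Without a filter on low counts there were 948 higher and 132 lower of 12240, and with 1 CPM in 4 libraries 1172 higher of 5258, where more gene IDs were tested. Scaled on the most abundant gene ID there were 706 and 6. On the same 886 gene IDs, the size factors of DESeq2 in edgeR gave 588 higher and 92 lower. DESeq2 itself gave 562 and 87. The move with DESeq2 thus came with its scaling more than with its test. Beyond this and the number of gene IDs tested, the cause of these moves was not tested. Leaving out each library in turn gave 393 to 577 higher and 120 to 257 lower calls, with both extremes of 577 and 120 without control TTGT. The difference of mean log10 totals then ran from 0.468 to 0.702, with an exact permutation p of 0.057 without any 1 FOG-3 library. The differences in genes at equal depth and in the read shares of the most abundant gene ID, of untested gene IDs and outside genes kept their direction and an exact permutation p of 0.0286 in the 9 alternatives run for each. Most of these left out 1 library. That could not reverse the direction, since every FOG-3 library already lay on the same side of every control. A p of 0.0286 is also the smallest these tests allow, so they are weak evidence of stability. Of the 401 higher gene IDs, which were chosen for a low control level, 268 had at most 3 control reads, so the size of their folds is poorly known. No paired analysis was possible because the columns carry no replicate number. The settings limited to protein-coding genes, and all settings for gene lists and the X chromosome, were not run, since no gene ID could be matched to a symbol.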

Other observations

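The controls differed in composition as well as depth. In the controls in order of depth (14964, 18676, 30631 and 74892 reads), the most abundant gene ID took 56.7%, 54.1%, 46.7% and 41.6% of gene-assigned reads. At equal depth they gave 1102, 990, 1470 and 1692 gene IDs, and the 401 higher gene IDs held 0.662%, 0.552%, 1.03% and 1.21% of their reads. With 4 controls no correlation was tested.

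One hypothesis, with its test chosen before its result was seen, is that reads of the higher gene IDs in controls may be carry-over of the FOG-3 profile at a fixed rate. The controls held 1424 such reads against 65565 in FOG-3 libraries, 2.17 per 100. If the rate were fixed, control and FOG-3 reads would keep one ratio over these gene IDs. Their chi-square per degree of freedom was 2.76. The highest value between any pair of FOG-3 libraries was 2.47, and the mark set for excluding a fixed rate was 2 times that value. These are unlike measures, because the pair value covered 1122 gene IDs with at least 20 reads in the pair. The higher gene IDs had a median of 2 control reads, and where spread exceeds counting error this chi-square grows with read number. The test decides neither way, for this reason and since the gene IDs were chosen for a low control level, which narrows their ratios.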
